A study of Capsicum chinense x Capsicum frutescens and Capsicum annuum with 4 samples.

How the data were processed

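Total RNA from leaves of inoculated chilli plants was labelled and hybridised, 1 sample per array, to a 1-colour Agilent tomato array. There were 2 arrays of the resistant and 2 of the susceptible line, grouped by the genotype given in the labels. The labels do not say whether the replicates came from separate plants or cultures, so p-values measure at most the spread between these arrays, which may be technical. The labels name biotin as the label, and the file headers describe a 1-colour scan.

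The deposited array files hold a brightness intensity for each spot, which Agilent Feature Extraction 10.7.3 made from the scan, per the submitters' processing notes and the file headers. Per the file headers, the processed signal is background-subtracted and spatially detrended, and weak spots share 1 lowest value per array. That lowest value was 7.59 and 4.32 on resistant arrays 1 and 2, and 6.77 and 11.28 on susceptible arrays 1 and 2. It was held by 67.9%, 74.0%, 79.7% and 78.7% of probes, in the same order. Signals were not scaled between arrays. The authors' deposited table gives an unsigned fold (a ratio), an up or down label, a p-value and a corrected p-value per probe. The test and scaling behind it are not given in the sources used here. The largest corrected p-value in the authors' deposited table, 0.00999546, equals the largest uncorrected one.

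Each array had 45220 spots, of which 1417 control spots were left out. The remaining 43803 spots held 43603 probes, 50 of them with 5 spots and the rest with 1. Spots of a probe were averaged on the log2 scale after leaving out outlier spots where the probe had other spots. No spot was saturated. Because fewer than 50% of probes were well above background on all 4 arrays, each array's log2 processed signal was reduced by its 75th percentile over the 1251 probes well above background on all 4. Those percentiles were 1634, 289.5, 498.3 and 507.6 for resistant 1, resistant 2, susceptible 1 and susceptible 2. The number of arrays limits the precision.

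Probes well above background on both arrays of at least 1 group were tested, 2436 in all. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with no trend and no robust prior), resistant minus susceptible, with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior carried 7.20 degrees of freedom beside 2 residual ones. A probe not well above background on any array of 1 group has only a bound there. Its fold is given as "at least", the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background, on normalised log2 values. The adjusted p beside it is that of the fit. Where a group lay at its arrays' lowest values, these were constants, after scaling -7.75 and -6.07 on resistant arrays 1 and 2. On susceptible arrays 1 and 2 they were -6.20 and -5.49. The group's spread in such a fit is the gap between these constants, so the p-value measures no spread between samples in that group. Levels printed per array, and their means and SDs, are processed signals before scaling.

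The fit was tested on simulated data with the spread of the real 2436 probes, 200 of them changed by known folds. It called 0% of the 50 probes changed 2-fold, 0% of those changed 4-fold, 14% of those changed 16-fold and 56% of those changed 64-fold, and 0 of 2236 unchanged probes. The ordinary t statistic with the same adjustment called 0 of the 200. The simulated noise was independent between probes, with the spreads shuffled among them. It had no lowest value and no filter on dim probes. Most real calls had a group not above background, so these shares do not describe them.

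Array identifiers are tomato probe numbers and transcript names, and the files pair them with product text only in the authors' deposited table. Of its 137 probes, 42 are listed as unknown and 13 name a product. Names were not guessed from accessions. The naming rule, fixed before the data were examined, took the 10 highest and the 10 lowest changes among probes past the threshold and above background on all 4 arrays, and up to 2 members in each direction per gene list. It also took the 3 brightest per direction among probes with only a bound, and the 5 largest changes per direction in the authors' deposited table. No probe above background on all 4 arrays had product text, so that part of the rule named none. LeGAD2, the phosphofructokinase-like probe and the PRLI-interacting factor A match are outside the rule and complete the 13. Gene lists were to be tested with camera from 5 members on.

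Alternatives were normexp background correction with an offset of 50 (on the median spot signal, which stood in for the mean), the percentile over all probes, median centring, quantile and cyclic loess normalisation. Others changed the filter on dim probes, the variance model, the test, the threshold and the replicate block, or left out each array. When an array was left out, the scaled values and the tested probes stayed as they were. Settings based on array position, local background and outlier spots were added after the data were seen.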

Results

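Leaf RNA was compared between chilli plants resistant and susceptible to pepper leaf curl virus (PepLCV), a begomovirus carried by whiteflies. Both kinds of plant had been exposed to whiteflies carrying the virus, and leaves were taken at the 3-leaf stage. The resistant line was BS-35, labelled as a cross of Capsicum chinense and Capsicum frutescens, and the susceptible line was IVPBC-535, a Capsicum annuum. RNA of 2 resistant and 2 susceptible samples was hybridised to tomato arrays with 43603 different non-control probes. The labels list no uninoculated sample, so the comparison is between inoculated plants of different genotype and species, and not between infected and healthy leaves.

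Few tomato probes gave signal with pepper RNA. Of the 43603 probes, 6589 and 3248 were well above background on resistant arrays 1 and 2, and 3216 and 1899 on susceptible arrays 1 and 2. The means were 4918.5 ± 2362 (SD, n = 2) for the resistant and 2557.5 ± 931 (SD, n = 2) for the susceptible arrays. No test of this difference was planned, and with 2 arrays against 2 an exact permutation test cannot give a two-sided p below 0.333. Dark-corner control spots, which carry no transcript probe, were well above background in 7.62% and 8.94% of cases on resistant arrays 1 and 2 and in 6.29% on each susceptible array, against 15.1%, 7.45%, 7.38% and 4.36% of probes. Of 320 spike-in control spots, 5 and 10 were well above background on resistant arrays 1 and 2, and 4 and 1 on susceptible arrays 1 and 2. Why so few spots gave signal was not tested. Only 1251 probes were well above background on all 4 arrays, and 34881 were on none. Over those 1251 probes the susceptible arrays correlated with each other at a Pearson r of 0.915, and the resistant arrays at 0.679. Resistant array 2 had a higher r with susceptible arrays 1 and 2, 0.804 and 0.808, than with the other resistant array. Resistant array 1 had an r of 0.737 with susceptible array 1, also higher, and of 0.604 with susceptible array 2. The lowest r values were thus all those of resistant array 1. These correlations are across probes, which are not independent replicates. All 4 arrays lay on 1 slide, the resistant samples at positions 1 and 2 and the susceptible ones at positions 3 and 4, so position and genotype cannot be told apart.

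The question the comparison addresses is which transcripts differ in level between resistant and susceptible leaves after inoculation. Plants of different species were read on tomato probes, so sequence match to a probe cannot be told apart from transcript level. Levels and folds below are therefore those of probe signal. Of the probes with a product name, 4 were bright on both susceptible arrays and not well above background on either resistant array. A probe matching part of a tobacco protein kinase, SRK (A_96_P162991), read 1051 ± 56.9 (SD, n = 2) in susceptible leaves, at least 50.3-fold above the resistant level (limma adjusted p = 0.000708). The probe for leucine aminopeptidase lap2 (A_96_P165596), a member of the family of enzymes that remove amino acids from the amino end of peptides, read 396.8 ± 149 (SD, n = 2), at least 18.3-fold higher (limma adjusted p = 0.00251). A probe with a 5% partial match to NADH-ubiquinone oxidoreductase chain 4, a subunit of the respiratory chain, read 368.9 ± 168 (SD, n = 2), at least 16.7-fold higher (A_96_P056076, limma adjusted p = 0.00233). The match is to an insect sequence, from the firebrat. These 3 calls ended with normexp background correction (limma adjusted p of 0.126, 0.303 and 0.318), with cyclic loess (0.0514, 0.0575 and 0.0543) and with an ordinary t statistic. The limits were 28.1-fold, 10.2-fold and 9.33-fold without resistant array 1, and 90.2-fold, 32.8-fold and 29.98-fold without resistant array 2.

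The fourth, a probe for a fruit-ripening protein (A_96_P243194), read 112.2 ± 28.8 (SD, n = 2) in susceptible leaves, at least 5.29-fold higher (limma adjusted p = 0.00834). Its call ended in 6 of 16 alternatives, among them normexp (limma adjusted p = 0.763), median centring (0.0526), the replicate block (0.0515) and the fit without susceptible array 2 (0.0938). Its limit was 2.95-fold without resistant array 1 and 9.48-fold without resistant array 2. It lies in the last column of the array, where local background was raised on the susceptible arrays. The array carries 6 more probes for the same transcript, and 3 of them were well above background on all 4 arrays. A_96_P188284 read 33061 and 14915 on the resistant and 14214 and 13925 on the susceptible arrays, a log2 change of 0.21 (SE 0.83, limma adjusted p = 0.914). A_96_P155761 had a log2 change of 0.23 (SE 0.83, limma adjusted p = 0.908), and A_96_P239673 of -1.57 (SE 0.79, limma adjusted p = 0.394). The last of these had the direction of A_96_P243194 and passed in 1 alternative, without resistant array 1 (log2 change -1.98, limma adjusted p = 0.0372). None of the 3 other lap2 probes was well above background on any array.

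In the opposite direction, 1 probe with a product name passed the threshold. A probe with a 6% partial match to a membrane protein of the bacterium Magnetospirillum (A_96_P258122) read 167.6 ± 148 (SD, n = 2) in resistant leaves and was not well above background in susceptible ones. That SD is of signals before scaling, 272.5 and 62.8, from arrays of unlike overall brightness. After scaling the log2 values on resistant arrays 1 and 2 were -2.58 and -2.20. Its level was at least 2.20-fold higher in resistant leaves (limma adjusted p = 0.0215). The call ended in 8 of 18 alternatives, among them normexp (limma adjusted p = 0.790), no filter on dim probes (0.173), the replicate block (0.0636) and the fits without susceptible array 1 (0.517) or 2 (0.215). A probe with a partial match to a far-red impaired response protein, a class of factors in phytochrome A light signalling, did not pass (A_96_P254917, at least 1.43-fold, limma adjusted p = 0.245), except without resistant array 1 (0.00245). It was well above background on both resistant arrays and on neither susceptible one.

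**Figure D1:**
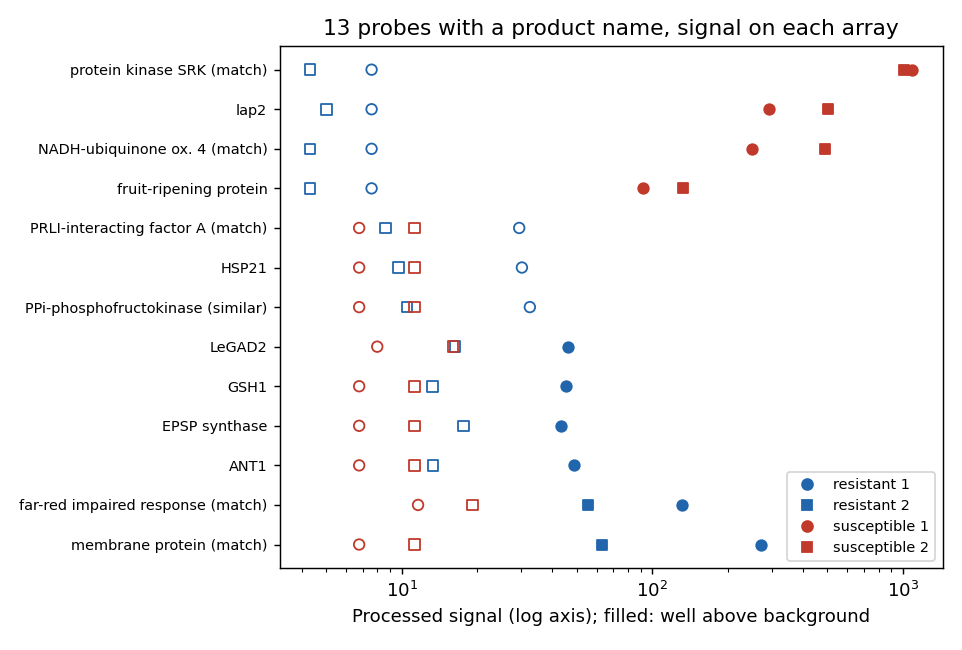
Processed signal (log axis) of the 13 probes with a product name on each of the 4 arrays; filled symbols are well above background and open ones are not. The probes for protein kinase SRK, lap2, the NADH-ubiquinone oxidoreductase match and the fruit-ripening protein are filled on both susceptible arrays, and only the far-red impaired response and membrane protein matches are filled on both resistant arrays.

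The other 7 product names belong to probes that were not well above background on both arrays of either group, so they were not tested and have no fold. The probe for ANT1, a MYB regulator of anthocyanin synthesis (A_96_P014321), read 48.97 and 13.37 on the resistant arrays and 6.77 and 11.28 on the susceptible arrays, which are the lowest values those susceptible arrays give. The same susceptible values were read for EPSP synthase of the shikimate pathway (A_96_P241974) and for GSH1, gamma-glutamylcysteine synthetase, which begins glutathione synthesis (A_96_P139782). Their resistant values were 43.3 and 17.6 for EPSP synthase and 45.4 and 13.3 for GSH1. Glutamate decarboxylase LeGAD2, which makes gamma-aminobutyric acid (A_96_P170914), read 46.2 and 16.3 on the resistant and 7.999 and 16.02 on the susceptible arrays. Each of these 4 probes was well above background on resistant array 1 only. The array holds 5 more LeGAD2 probes, of which A_96_P087294 and A_96_P166096 were well above background on resistant array 1 only (74.5 and 74.0) and A_96_P218624 on resistant array 2 only (68.2). Of 4 more GSH1 probes, A_96_P000996 and A_96_P244675 were so on resistant array 1 only (260.5 and 49.4). The other LeGAD2 and GSH1 probes, and the 1 other EPSP synthase probe, were so on no array. The chloroplast heat shock protein HSP21 (A_96_P001001), a pyrophosphate-dependent phosphofructokinase-like probe (A_96_P028166) and a PRLI-interacting factor A match (A_96_P251702) were well above background on no array.

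Of the 41 gene lists fixed for defence, hormone, stress and metabolic functions, 2 had a member with text. ANT1 fell in the phenylpropanoid list and HSP21 in the heat shock list, and neither probe could be tested. A list test needed 5 tested members, and no list had any. The number of gene lists changed therefore has no value here. Product text came only from the authors' deposited table, which describes 95 of its 137 probes in some way, most of them as clones.

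Over all tested probes, 230 of 2436 passed a limma adjusted p of 0.05, of which 215 were higher in susceptible and 15 higher in resistant leaves. All 230 had a fitted change of at least 2-fold, but 196 of them were above background in 1 group only, and for 2 of these the bound was under 2-fold (A_96_P033451, at least 1.73-fold, and A_96_P098892, at least 1.91-fold, both higher in resistant leaves). The calls of these 2 ended in 10 of 19 and 9 of 18 alternatives, among them the fits without susceptible array 1 (limma adjusted p of 0.710 and 0.623) or 2 (0.329 and 0.276). Of the 215, 182 were above background on both susceptible and neither resistant array, among 203 tested probes of that kind. Of the 15, 14 were above background on both resistant and neither susceptible array, among 323 tested. The scaled lowest values averaged lower on the resistant arrays (-7.75 and -6.07) than on the susceptible ones (-6.20 and -5.49). At such values, changes higher in susceptible leaves widen and those higher in resistant leaves narrow. A 2-fold change with no test gave 475 probes higher in resistant and 546 in susceptible leaves. The 215 and 15 therefore do not measure a balance of expression. Among the 1251 probes measured on all 4 arrays, 8 were higher in susceptible and 1 in resistant leaves.

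A probe for a tomato leaf cDNA clone (A_96_P252497, transcript AK246954) was among those 8. It read 180.8 and 126.6 on the resistant arrays and 34474 and 63334 on the susceptible arrays, a 422.4-fold difference (limma adjusted p = 0.000617). 2 further probes of this transcript were also higher in susceptible leaves (limma adjusted p of 0.01001 and 0.0369). A_96_P092489 read 43.1 and 4.32 on the resistant and 208.1 and 146.4 on the susceptible arrays, and A_96_P001621 read 61.8 and 5.31 against 94.5 and 173.8. On resistant array 2 neither was well above background, so no fold is given. The array holds 3 more probes of this transcript. A_96_P092484 and A_96_P130757 were well above background on no array, and A_96_P132132 was so on resistant array 2 only, where it read 41.2 against 10.3 and 21.4 on the susceptible arrays. Another leaf clone, AK247057, had both of its probes higher in susceptible leaves. They differed by at least 31.3-fold (A_96_P103299, limma adjusted p = 0.00100) and at least 3.57-fold (A_96_P028446, limma adjusted p = 0.0141). The call of A_96_P252497 ended with cyclic loess (limma adjusted p = 0.0525) and with an ordinary t statistic, and those of A_96_P092489, A_96_P001621, A_96_P103299 and A_96_P028446 in 6, 11, 3 and 7 of 19 alternatives. Without susceptible array 1 or 2 the calls of A_96_P092489 (limma adjusted p of 0.207 and 0.100), A_96_P001621 (0.245 and 0.619) and A_96_P028446 (0.201 and 0.0980) ended. Without resistant array 1 the difference of A_96_P252497 was 212.5-fold and the limits of A_96_P103299 and A_96_P028446 were 17.4-fold and 1.99-fold. Without resistant array 2 they were 839.6-fold, 56.0-fold and 6.40-fold. The clones were singled out after their values were seen, because several probes of each passed.

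The 1 probe measured on all 4 arrays and higher in resistant leaves, A_96_P031441, read 12143 and 7611 on the resistant and 585.9 and 79.1 on the susceptible arrays, a 32.7-fold difference (limma adjusted p = 0.0175). A_96_P042826 read 5705 and 66.7 on the resistant arrays and was not well above background on the susceptible arrays, at least 10.4-fold (limma adjusted p = 0.0146). The call of A_96_P031441 ended in 8 of 20 alternatives, among them the fit on the 1251 probes above background on all 4 arrays (limma adjusted p = 0.0515), where none was higher in resistant leaves, the replicate block (0.169) and the fit without susceptible array 2 (0.285). Its difference was 61.4-fold and 17.4-fold without resistant array 1 or 2, and 89.7-fold and 11.9-fold without susceptible array 1 or 2. The limit of A_96_P042826 was 2.66-fold without resistant array 1 and 40.3-fold without resistant array 2. The call of A_96_P042826 ended in 5 of 17 in its own direction, and with normexp the direction turned (log2 change -0.21, limma adjusted p = 0.982). Neither has a name in the files, and both were chosen after their values were seen.

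**Figure D2:**
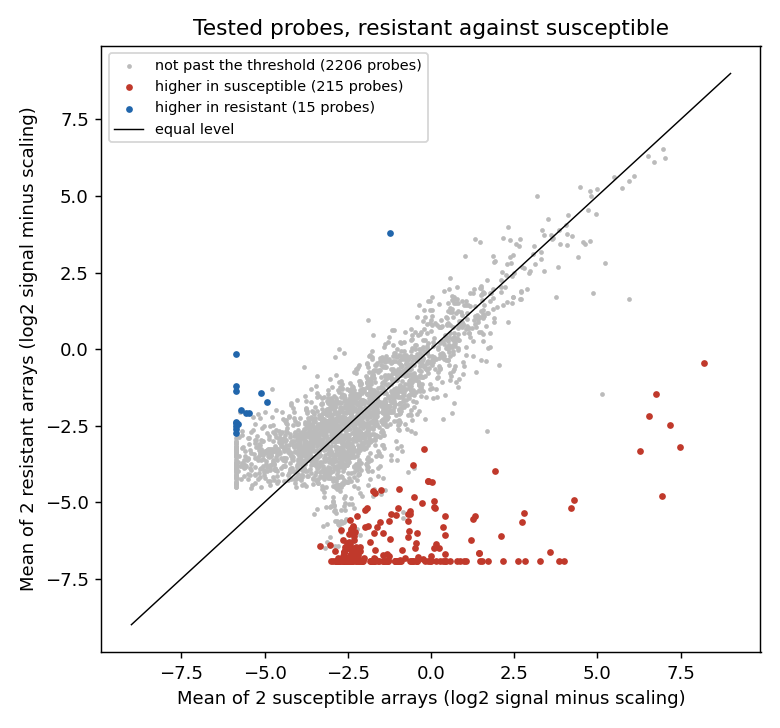
Mean normalised log2 signal of the 2 susceptible arrays (x axis) and the 2 resistant arrays (y axis) for the 2436 tested probes, coloured by the limma result. The 215 probes higher in susceptible leaves lie mostly along the lowest resistant values, and the 15 higher in resistant leaves mostly at the lowest susceptible values.

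The counts moved with the processing. With normexp background correction 12 probes passed, with cyclic loess 17, with median centring 118, with the replicate number as a block 81 and with an ordinary t statistic 0, and leaving out 1 array gave from 103 (susceptible array 1) to 614 (resistant array 2).

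The calls were not spread evenly over the array. In the last column, 38 of 90 tested probes were higher in susceptible leaves, 42.2%, against 177 of 2346 in the other columns, 7.54%. All 38 had a local background marked as an outlier on at least 1 array, as had 87 of the 90 tested there. In other columns 37 of the 177 had one, 20.9%, against 24.9% of tested probes. Without the last column 186 probes passed, 172 higher in susceptible and 14 in resistant leaves. This setting was chosen after the data were seen.

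**Figure D3:**
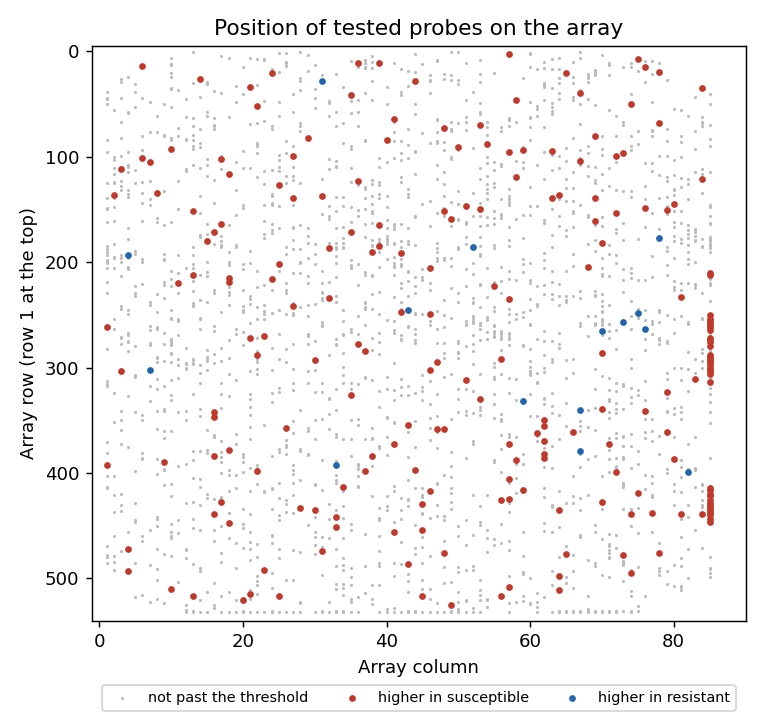
Array column (x axis) and row (y axis) of the 2436 tested probes, with those higher in susceptible leaves in red and those higher in resistant leaves in blue. In the last column, column 85, 38 of 90 tested probes are red.

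The authors' deposited table lists 137 probes with a fold of at least 2 between resistant and susceptible plants, 65 as up and 72 as down, and does not say which group is the numerator. Its folds were recovered from the processed signals when each array was scaled to the 75th percentile of all probes, to within 0.000678 on the log2 scale, with the sign opposite to resistant minus susceptible. All 65 probes listed as up were thus higher on the arrays labelled susceptible, and all 72 listed as down were higher on the arrays labelled resistant. The files do not settle whether the table sets susceptible over resistant or the array labels were exchanged, and in the latter case every direction given here, the 215 and 15 probes included, would turn. Among the 77 listed probes tested here, 0% had the table's sign if up is read as higher in resistant plants and 100% if it is read as higher in susceptible plants. This compares treatments of the same arrays and is no independent evidence.

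In the authors' deposited table, protein kinase SRK is up 166.3-fold, lap2 56.3-fold, the NADH-ubiquinone oxidoreductase match 55.3-fold and the fruit-ripening protein 17.5-fold. The table lists the membrane protein match as down 16.5-fold, the far-red impaired response match 6.28-fold, EPSP synthase 3.48-fold, ANT1 3.23-fold and GSH1 3.10-fold. Of the 65 listed as up, 61 passed in limma and 4 were not tested. Of the 72 listed as down, 5 passed, and 56 were not well above background on both arrays of either group. The median signals of the 72 were 42.3 and 13.9 on the resistant and 6.77 and 11.28 on the susceptible arrays. An unadjusted p under 0.01 from an ordinary t statistic with a 2-fold change, on the same scaling, gave 136 probes, and all 136 are in the table. At any fold 243 probes had such a p, fewer than the 436 expected with no change. That expectation assumes evenly spread p-values, which probes at the lowest values do not give. After Benjamini-Hochberg adjustment over the 43603 probes, 6 had an adjusted p under 0.05.

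**Figure D4:**
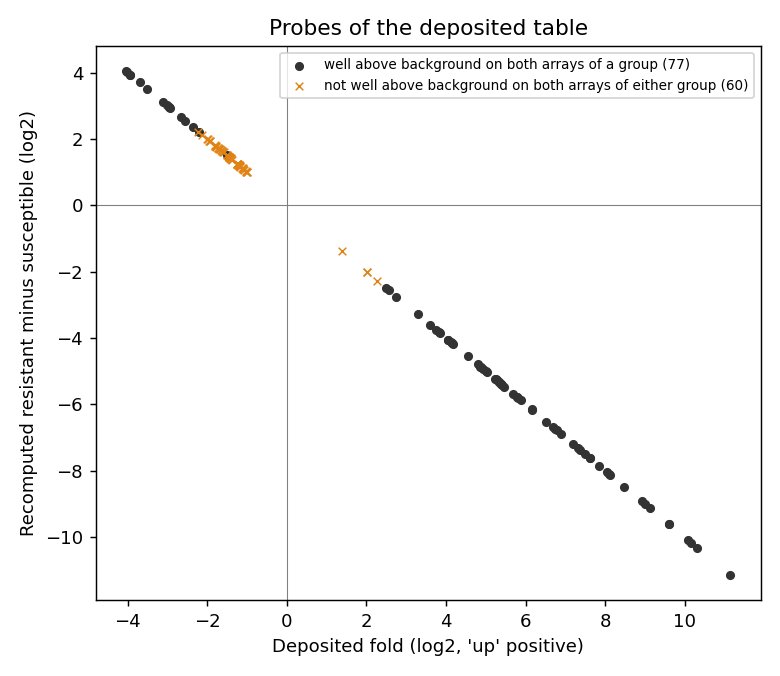
Log2 fold in the authors' deposited table, with up as positive (x axis), against resistant minus susceptible recomputed with each array's 75th percentile of all probes (y axis), for 137 probes. The points lie on 1 falling line, and the 60 crosses, not well above background on both arrays of either group, are mostly probes the table lists as down.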

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

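All tests in this part were chosen after the results they bear on were seen. Control spots that should give no signal were above background in places. Of 604 dark-corner spots, 46 and 54 were well above background on resistant arrays 1 and 2, and 38 and 38 on the susceptible arrays. On resistant array 2 and susceptible array 2 these shares, 8.94% and 6.29%, exceed the 7.45% and 4.36% of probes that were. Of 153 negative-control spots, 4 were well above background on resistant array 2 and 4 on susceptible array 1. These exceed 3, a fixed count above which such signals were flagged, with no test. Of probes well above background on a single array, which enter no comparison, some had signals over 10000. These were 4 of 3857 on resistant array 1 and 4 of 1138 on resistant array 2, the brightest 102626 and 430263. On susceptible arrays 1 and 2 they were 2 of 538 and 1 of 120, the brightest 20618 and 132194. The susceptible counts were not over 3, but they come from fewer probes, so the limit does not set the groups apart.

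The excess of calls in the last array column was weighed between background at the array edge and expression. The last column's median local background was 59 and 55 on the susceptible arrays against 26 and 29 in the other columns, a ratio of at least 1.90, and on the resistant arrays the ratio was 0.96 and 1.06. Of the probes in the last column, 41.6% and 31.5% were well above background on susceptible arrays 1 and 2, against 7.03% and 4.09% of those in others. Dark-corner spots lie only at the ends of that column. There they were well above background in 22.7% against 4.28% in other columns on susceptible array 2, but in 7.58% against 6.13% on susceptible array 1. At the first end they were so in 0% and 5.88% on susceptible arrays 1 and 2, with a median local background of 28 and 70, and at the last end in 15.6% and 40.6%, with 85 and 80, so whether raised background lit the probes of that column stays open. Expression alone does not account for the excess, since 42.2% of tested probes there were called against 7.54% elsewhere (two-sided Fisher's exact test, p = 2.51e-18), while probes of 1 transcript shared a column in 1.22% of pairs against 1.18% by chance, though individual calls there, such as the fruit-ripening protein probe, may still hold expression.

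The 177 calls higher in susceptible leaves outside the last column were weighed between local artefacts, single-probe signal and a difference of the transcript. Of the 177, 37 had an outlying local background, 20.9% against 24.9% of tested probes in those columns. The median distance to the nearest other call was 5.22 spot columns, inside the central range of 4.50 to 6.02 from random tested probes. The calls were thus no more crowded than other tested probes. Those were themselves picked for signal and may share local artefacts, so artefacts that light neighbouring spots stay open. 4 transcripts had more than 1 call (AK246954, AK247057, AF148534 and TA44569_4081), against 2.56 in random draws of tested probes (permutation p = 0.252, one-sided) and 0.602 in draws among probes with a tested sibling (permutation p = 0.00099, one-sided), a draw added after the first was known, so the outcome depends on the draw and a transcript-level difference stays open. Sibling probes were well above background on both susceptible arrays in 16.2% of cases (19 of 117) against 36.3% (69 of 190) for siblings of probes of like brightness, which suggests a single-probe part, but those matched probes were picked for signal in both genotypes, so this does not decide. Genotype, sequence match to the tomato probes and slide position are confounded here.

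Probes the authors' deposited table lists as down were weighed between scaling and expression. On both susceptible arrays the 75th percentile of all probes equals the lowest signal (6.77 and 11.28), so that weak probes become equal there. Of the 72 listed as down, 60 have that lowest value on both, 83.3%, against 69.7% of all probes. For these 60 the susceptible spread under this scaling was 0 by construction, so their p-values measure spread between the resistant arrays alone. The log2 ratio of resistant array 1 to 2 over the 72 had a median of 1.62 (quartiles 1.48 and 1.71). The log2 ratio of these arrays' 75th percentiles was 1.60, so this scaling brought the resistant values together as well. With the percentile over probes above background on all arrays, 0 of the 72 had an unadjusted p under 0.01 and 36 a 2-fold change, while of the 65 listed as up 15 and 65 did. With the spread alone exchanged and the difference kept, 1 of the 72 and 12 of the 65 had such a p. The median pooled SD within groups rose from 0.0759 to 0.565 for those listed as down, and from 0.454 to 0.848 for those listed as up. The p-values under 0.01 of those listed as down thus depend on the first scaling. The listed probes were picked by passing under it, and both those listed as up and as down lose most of their p-values under 0.01. These counts therefore do not decide whether scaling alone put them in the table. Higher expression in the resistant plants stays open too, as 5 passed in limma and 56 could not be tested.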

How the results depend on the processing

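No tested probe with a product name turned direction under any alternative. Product text came only from the authors' deposited table, whose probes were listed for a fold of at least 2 on these same arrays. Their kept direction is therefore no independent evidence. Of 109 values of these probes under alternatives, 85 kept their side of the threshold, 23 no longer passed and 1 newly passed (the far-red impaired response match without resistant array 1). Of the 23, 5 each were under normexp, cyclic loess and the ordinary t statistic. Of the other probes named, A_96_P042826 turned with normexp (-0.21), and the fruit-ripening siblings A_96_P188284 and A_96_P155761, which pass in no setting, turned without resistant array 2 (-0.47 and -0.43, against 0.88 and 0.88 without resistant array 1), while the third, A_96_P239673, newly passed without resistant array 1 (-1.98, limma adjusted p = 0.0372). The cause of the moves below was not tested unless stated. Against 230 probes (15 higher in resistant, 215 in susceptible), normexp gave 12 (0 and 12), median centring 118 (4 and 114) and cyclic loess 17 (0 and 17), and these were the same numbers at least 2-fold. The percentile over all probes gave 236, of which 38 were higher in resistant. The ordinary t statistic gave 0 in each direction, with 315 probes at an unadjusted p under 0.05, against 393 in limma; its 2 degrees of freedom gave no call in the simulated data either. Testing only probes above background on all 4 arrays left 1251 probes and gave 7 (0 and 7). A threshold of 0.01 gave 132 (2 and 130), and a 2-fold change with no test 1021 (475 and 546). Leaving out probes with an outlying local background, chosen after the data were seen, gave 142 (7 and 135). Leaving out the last column or the outer frame, also chosen then, gave 186 and 188. Quantile normalisation, no filter, the trend, the robust prior and the removal of probes with an outlier spot gave between 213 and 235. Removal of saturated probes moved nothing, as there were none. The median log2 change of tested probes moved from 0.01 to 0.61 with the percentile over all probes and to 0.21 with cyclic loess. With normexp, which also changes the background correction and the input signal, it was -0.11. Without the filter on dim probes the median over all 43603 probes was -1.06.

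Leaving out 1 array gave 103 to 614 probes (2 to 198 higher in resistant, 101 to 417 in susceptible). Without resistant array 1 the count was 604 and without resistant array 2 it was 614, against 103 and 111 without susceptible array 1 or 2. The lone array of a group is then assumed to vary like the other group.

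With the replicate block, 81 probes passed, 0 higher in resistant and 81 in susceptible, where limma gave 450 at an unadjusted p under 0.05. The samples share only a number: with 2 pairs, the deviations of same-numbered arrays from their group means correlated at r = 0.43 across 1251 probes.

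The sign agreement with the deposited table was 2.60% and 97.4% under normexp for the readings of up as higher in resistant and in susceptible plants, and 0% and 100% under quantile normalisation and median centring. With the scanner's flag for positive and significant signal in place of well above background, 13967 and 11302 probes counted on the resistant and 8840 and 9250 on the susceptible arrays. The slide block was not run, as there was 1 slide, and no gene list alternative gave a value. Weak signal limits most results: only 1251 of 43603 probes were above background on all 4 arrays.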

Other observations

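The tests in this part were chosen after the data were seen. A set of 4 transcripts had several probes higher in susceptible leaves. Beside the leaf clones AK246954 and AK247057, AF148534 had 2 such probes (at least 5.09-fold and 3.87-fold, limma adjusted p = 0.0102 and 0.0119) and TA44569_4081 had 2 (A_96_P102619, limma adjusted p = 0.0459, and A_96_P172164, at least 4.89-fold, limma adjusted p = 0.0462). A_96_P102619 read 7.59 and 46.1 on the resistant and 536.2 and 565.8 on the susceptible arrays, the first of these at that array's lowest value, so no fold is given. The calls of A_96_P102619 and A_96_P172164 ended in 9 and 12 of 19 alternatives, and those of the AF148534 probes in 7 of 19 each. Without susceptible array 1 or 2 the calls of A_96_P172164 (limma adjusted p of 0.227 and 0.147) and of the AF148534 probes A_96_P078099 (0.143 and 0.0980) and A_96_P001246 (0.157 and 0.0938) ended. The limits of A_96_P172164, A_96_P078099 and A_96_P001246 were 2.73-fold, 2.84-fold and 2.16-fold without resistant array 1, and 8.76-fold, 9.13-fold and 6.93-fold without resistant array 2. AF148534 has 3 more probes on the array, none of them well above background on any array. The files give neither of these transcripts a product.

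Of the 23 different tested sibling probes of calls outside the last column, 9, all of these 4 transcripts, were themselves higher in susceptible leaves. Over 104 transcripts with a pair of probes above background on all 4 arrays, the log2 changes of the pair correlated at a Pearson r of 0.46 and a Spearman rho of 0.59, across transcripts, which are not independent replicates.

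The 4 arrays can be split into pairs in 3 ways. The split by genotype gave 230 probes and the highest of the others 0, and 1 of the 3 splits, the real one, gave as many. 3 splits are too few for a share under 0.05. By the unadjusted p under 0.01 and 2-fold change that recovered the deposited table, the split by genotype gave 136 probes and the others 91 and 53.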
